A study of Mus musculus with 4 samples.

How the data were processed

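Double positive thymocytes, the CD4 and CD8 expressing stage of T cell development in the thymus, were profiled from 4 mice on Affymetrix mouse expression arrays, 1 array per mouse. The labels put 2 mice in the Ikf/f CD4-Cre- group (Cre-negative) and 2 in the Ikf/f CD4-Cre+ group (Cre-positive), in which Cre recombinase from a CD4-Cre transgene is meant to delete Ikaros, the product of Ikzf1. Each sample carries its own mouse number, so the replicates are separate animals. How the cells were isolated, the age and sex of the mice, and the dates of the hybridisations are not given in the sources used here. Total RNA was extracted with a column kit and labelled with biotin in a 2-cycle amplification, per the labels' protocols, which list several amounts of starting RNA, each with a code, without tying them to a sample. Whether the 4 arrays were handled as 1 batch is therefore not given in the sources used here, and a batch that coincided with the groups could not be separated from them.

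The deposited table holds 1 value per probe set and array. The values, log2 signals, were made by the authors with RMA (robust multi-array average, which subtracts background, normalizes the arrays to a common distribution and summarises the probes of a set), per the submitters' processing notes, with no version stated. They lay between 2.18 and 14.4 and were taken as logarithms to base 2 because that is the scale RMA returns; no label states the base of the logarithm. The scanner files were not used here, so background and normalization could not be varied before summarisation. Array medians over all probe sets were 5.19 and 5.22 in Cre-negative samples 1 and 2 and 5.23 and 5.25 in Cre-positive samples 1 and 2. RMA gives no counts, so precision is limited by the number of arrays, 2 per group.

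Gene names came from the platform annotation, matched to a current RefSeq gene table by Entrez identifier. Of 45037 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none; 34741 matched the current table and 0 symbols changed. Only probe sets with 1 symbol entered the gene comparison. Each of the 18193 genes was represented by its probe set with the highest mean over the 4 arrays, and 11639 genes whose mean was at or above the 40th percentile of all named probe sets (4.76) were kept. No genome build is named with the values, so no coordinates are given.

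The Cre-positive and Cre-negative arrays were compared with limma (version 3.58.1, lmFit and eBayes without trend, in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over the kept genes, and a gene was called at an adjusted p under 0.05. Differences are Cre-positive minus Cre-negative on the log2 scale, with the moderated standard error (SE). The fit had 2 residual degrees of freedom and a prior of 3.59. For a single gene an exact permutation test of 2 against 2 arrays cannot give a p below 0.333, so calls rest on the spread shared across genes. Gene lists were tested with camera at a preset correlation of 0.01, again with camera at a correlation estimated for each list, and with fry, which asks whether a list's genes move one way on balance, each with Benjamini-Hochberg adjustment over the 20 lists of at least 4 kept members. At the preset correlation the degrees of freedom of camera come from the number of genes. Its p then does not measure the spread between the 2 mice of a group. At an estimated correlation camera refers to the 2 residual degrees of freedom, so a list can miss the threshold without correlated genes. Of the 22 lists, the erythroid markers and sex-linked genes were only shown.

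The groups, lists, test, filter, alternatives and the rule for named genes were fixed before the data were examined. The rule named Ikzf1; in each direction the 12 called genes with the largest difference whose arrays did not overlap between groups; a fixed set of thymocyte genes; and up to 4 members per list with the smallest p, with every called member. Symbols of predicted genes and cDNA clones were passed over, 3 among the higher and 2 among the lower genes. Some listed genes were not analysed here. Counts of list genes, also where called measured, are of members kept by the filter.

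The procedure was tested on simulated data for the comparison of Cre-positive with Cre-negative arrays, with 11639 genes of which 200 were changed. It recovered 66 of 100 genes changed by 1 and 97 of 100 changed by 2 on the log2 scale, and 18 of its 181 calls were false. The simulated noise was normal and independent between genes, with variances drawn from the prior that limma fitted. Differences that many genes of an array share were absent, so these rates need not hold for the real arrays. Alternatives varied the filter, the choice of probe set, the variance prior, array scaling, array weights, the sample number as a block, and left out each array in turn. A covariate for the proliferation list was added after the data were seen. Figures were drawn with matplotlib 3.10.9.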

Results

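Gene expression was measured in double positive thymocytes from 2 Cre-negative mice, which keep Ikaros, and 2 Cre-positive mice, in which CD4-Cre is meant to delete it. Ikaros is a zinc finger DNA-binding protein of lymphocyte development, and the design asks which transcripts differ once it is removed at this stage. Every mouse was Ikf/f, with no Cre-positive mice of another Ikzf1 genotype. Effects of Cre itself therefore cannot be told apart from those of Ikaros loss. Values are RMA log2 signals. Pearson's r over all probe sets was 0.992 between the Cre-negative arrays and 0.994 between the Cre-positive arrays, against 0.984 to 0.988 between arrays of different groups; these are correlations across probe sets, which are not independent replicates. No array was a copy of another: any pair shared at most 166 identical values out of 45037.

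Ikzf1, the targeted gene, fell by 1.53 on the log2 scale in the Cre-positive mice. Its brighter probe set read 12.40 and 12.08 in Cre-negative samples 1 and 2 and 10.80 and 10.62 in Cre-positive samples 1 and 2, with means of 12.24 ± 0.23 and 10.71 ± 0.12 (SD, n = 2 each). The difference had an SE of 0.16 and an adjusted p of 0.024 in limma with Benjamini-Hochberg adjustment. A dimmer Ikzf1 probe set differed by −0.22, with means of 5.77 and 5.54, and did not pass. With the mean of both probe sets Ikzf1 differed by −0.88 (limma adjusted p = 0.037). The deleted part of the gene and the positions of the probes are not given in the sources used here, so this check of the labels rests on lower signal and gives no measure of the deletion. With any single array left out the difference lay between −1.69 and −1.37, and its adjusted p rose to between 0.0717 and 0.164.

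The largest differences were increases, and several took genes from near the bottom of the signal range to well above it. Iigp1, which encodes an interferon-inducible GTPase, rose by 4.44 ± 0.38 (difference ± SE, n = 2 per group), from a mean of 4.22 to 8.66. Ppic, the prolyl isomerase cyclophilin C, rose by 4.29 ± 0.13, from 3.93 to 8.21, and Jchain, the joining chain of polymeric immunoglobulins, rose by 3.89 ± 0.16. Gimap4, a GTPase of lymphocytes, rose by 3.71 ± 0.26 and the adhesion protein gene Mpzl2 by 3.50 ± 0.33. The collagen receptor kinase gene Ddr1 rose by 3.22, but 1 of its 6 probe sets differed by −0.12, the value left without probe sets that can bind several transcripts. Gimap4 under that restriction differed by 2.08 (limma adjusted p = 0.0514). The ubiquitin ligase gene Trim2 rose by 3.20 and the membrane metalloproteinase gene Mmp14 by 3.05, though the lowest of the 3 Mmp14 probe sets differed by 0.44. The lysosomal protease gene Ctss rose by 2.98 and the interferon-inducible gene Rtp4 by 2.71. The calcium-binding protein gene Tesc rose by 2.69 and the lysozyme gene Lyz1 by 2.65. The Lyz1 and Lyz2 transcripts are near-identical, so their probe sets may not tell them apart. Adjusted p-values of these 12 genes in limma with Benjamini-Hochberg adjustment ran from 0.00161 (Ppic) to 0.0453 (Tesc). Iigp1, Ppic, Jchain, Mpzl2 and Trim2 had Cre-negative means under the signal filter of 4.76, so the sizes and order of their differences are uncertain.

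Decreases were smaller. Fbxw10, an F-box protein gene, fell by 2.50 ± 0.11 (difference ± SE), from 7.95 to 5.45. Tespa1, a thymocyte protein linked to T cell receptor signalling in positive selection, fell by 1.48 ± 0.12, and Itpkb, the inositol trisphosphate 3-kinase needed for the same selection step, fell by 1.13 ± 0.13. Ankrd6 fell by 1.38, the lysosomal channel gene Mcoln3 by 1.34, Gramd3 by 1.32, Trim16 by 1.24, the protease gene Adamts6 by 1.22, Glipr1 by 1.21, Fgd3 by 1.21 and the deubiquitinase gene Stambpl1 by 1.19. The rule that named these 11 genes required both Cre-positive arrays to lie below both Cre-negative arrays. Their adjusted p-values in limma ran from 0.00361 (Fbxw10) to 0.0453 (Fgd3). Fgd3 and Itpkb each had a further probe set at −0.03 and −0.05. With the mean of all probe sets Fgd3, Itpkb, Mcoln3 and Trim16 no longer passed.

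**Figure D1:**
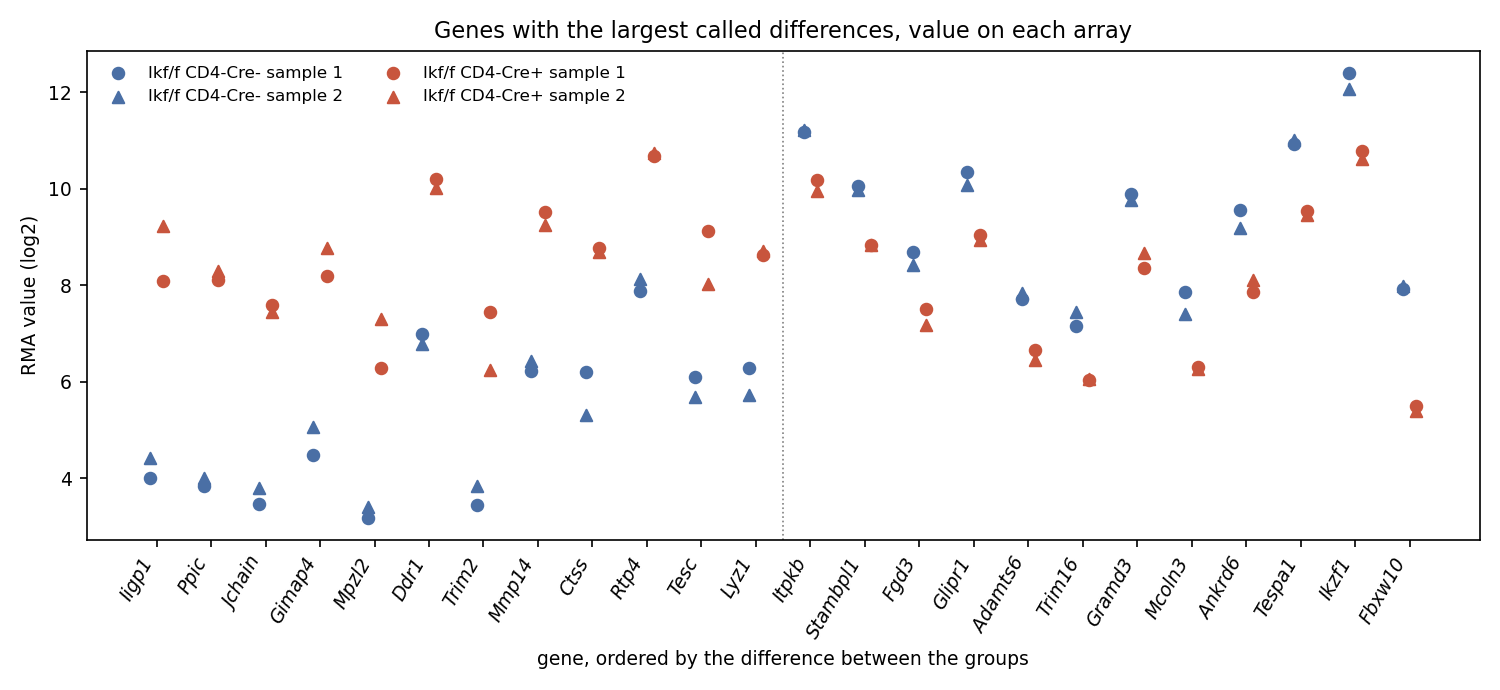
RMA value on the log2 scale (vertical axis) of each array for the 12 called genes with the largest increase and the 12 with the largest decrease, Ikzf1 included. Blue and red points are Cre-negative and Cre-positive arrays, circles and triangles samples 1 and 2. The groups do not overlap for any gene plotted because the rule that chose the genes required it. Iigp1 moved from 4.02 and 4.42 to 8.08 and 9.24.

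In all, 160 of the 11639 genes passed in limma, 129 higher and 31 lower in the Cre-positive mice, so 80.6% of calls were higher. Of these, 99 higher and 16 lower genes differed by at least 1 on the log2 scale. At an unadjusted p under 0.05, 1665 genes were higher and 732 lower. The groups did not overlap for 6153 genes (52.9%), where chance gives 33.3% on average over the possible splits of the arrays. Genes on the same arrays are not independent, so a difference shared by many genes can raise the share of a single split. The spread of this share was not measured, so 52.9% was not tested against chance. Centring each array on its median, which moved the median difference of all genes from 0.06 to −0.07, left 123 calls with 75 higher and 48 lower (61.0% higher), 106 of them shared. Of 56 called genes named in the text, 12 no longer passed after centring, though their differences stayed near their size and their adjusted p in limma lay between 0.0506 and 0.0676. Tesc differed by 2.56, Myc by 1.36, Cd53 by 1.19, Pmaip1 by 0.74, Gzma by 1.30, Irf9 by 0.97, H2-Ab1 by 1.46, Irf8 by 0.95 and Pdgfrb by 0.92. The number of calls depended on each array: it was 14 without Cre-negative sample 1, 3 without Cre-negative sample 2, 43 without Cre-positive sample 1 and 99 without Cre-positive sample 2.

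Interferon response genes were higher in the Cre-positive mice. Of 15 kept by the filter, 7 rose, 0 fell and 8 did not pass over all genes, and 13 passed adjusted over the list alone. Ifit1, which binds viral RNA, rose by 2.63 ± 0.16, Usp18, which restrains interferon signalling, by 2.49 ± 0.15, and the RNA sensor gene Ifih1 by 2.01 ± 0.12 (difference ± SE). Oas1a rose by 1.65 and Irf9 by 1.10. Xaf1 rose by 1.72, but its other probe set differed by −2.49. The median difference of the list was 1.10 (camera adjusted p = 3.18e-09; adjusted p = 0.444 with an estimated correlation; fry adjusted p = 0.0116), and it was 0.70 with the mean of all probe sets of a gene.

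As lists, markers of macrophages, granulocytes and dendritic cells were also higher. Of 13 macrophage and granulocyte markers, 2 rose, Ctss and the lysozyme gene Lyz2 (1.85 ± 0.17, SE), 0 fell and 11 did not pass, while 6 passed adjusted over the list alone; Tyrobp differed by 0.82 and the complement gene C1qa by 1.11. The list median was 0.90 (camera adjusted p = 0.000251; adjusted p = 0.456 with an estimated correlation; fry adjusted p = 0.0314). Of 10 dendritic cell markers, the MHC class II gene H2-Ab1 rose by 1.58 ± 0.22 and the transcription factor gene Irf8 by 1.08 ± 0.16, 0 fell and 8 did not pass, while 6 passed adjusted over the list alone. H2-Aa differed by 2.25 and H2-Eb1 by 1.68. That list had a median of 0.98 (camera adjusted p = 0.00308; adjusted p = 0.456 with an estimated correlation; fry adjusted p = 0.117), and its call was lost without probe sets that can bind several transcripts (adjusted p = 0.096). Without the filter on low values the macrophage and granulocyte median was 0.695 and the dendritic median 0.58. With the filter at the 60th percentile the dendritic median was 1.63. The granulocyte genes S100a8 and S100a9, chosen after their values were seen, read 8.38 and 7.14 in Cre-positive sample 2, against 4.52 and 3.74 in Cre-positive sample 1.

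Notch target genes were higher as a list. Of 12 measured, Myc, a growth regulator, rose by 1.49 ± 0.20 (SE), 0 fell and 11 did not pass, while 6 passed adjusted over the list alone. Ptcra, which encodes the pre-T cell receptor alpha chain, differed by 1.16 ± 0.18 (limma adjusted p = 0.054), Notch1 by 1.10 ± 0.19 (adjusted p = 0.0657) and Hes1 by 0.62. Dtx1 differed by 1.93 ± 0.43, but its other probe set by −0.57, and Notch3 differed by 0.37. Il2ra differed by −0.40, with its other probe set at 0.06. Its arrays overlapped between the groups, at 5.62 and 5.37 in Cre-negative and 4.78 and 5.40 in Cre-positive samples 1 and 2. The list median was 0.38 (camera adjusted p = 0.00989; adjusted p = 0.456 with an estimated correlation; fry adjusted p = 0.0277), and without probe sets that can bind several transcripts its adjusted p was 0.347. The Notch median was 0.26 with arrays centred on their median and 1.13 with the filter at the 60th percentile. Of 9 genes of the double negative and pre-T cell receptor stage, 0 passed over all genes in limma (2 at an unadjusted p under 0.05) and 2 adjusted over the list alone, Ptcra and Cd44 (−0.61); the list median was −0.04 (camera adjusted p = 0.362). Igll1 differed by −0.02 and by 0.13 in its other probe set. Of 12 stem and progenitor genes, 0 passed in limma (3 at an unadjusted p under 0.05) and 2 passed adjusted over the list alone, Eng (0.98) and Angpt1 (0.53), with Slamf1 at −0.45. Their median was 0.00, their mean 0.08 and the camera direction lower (adjusted p = 0.865), and the median was −0.125 after centring. Cd34 lay below the filter, between 3.11 and 3.25 on all arrays.

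Genes that define the double positive stage kept high signals in both groups and were slightly lower as a list. Rag1, a subunit of the recombinase, averaged 13.44 and 13.33 in Cre-negative and Cre-positive mice, Cd4 10.56 and 10.42, and Cd8a 13.02 and 12.71. Of 20 measured, 0 passed in limma over all genes or adjusted over the list alone (4 at an unadjusted p under 0.05); the largest differences were Slc7a11 at 0.82 and Cd1d1 at −0.66, and Cd8b1 differed by −0.29. Probe sets of Cd8a ranged from −0.32 to 0.10. The list median was −0.17 (camera adjusted p = 0.00458; adjusted p = 0.456 with an estimated correlation; fry adjusted p = 0.0199), and it was −0.30 with arrays centred on their median. Of 23 T cell receptor signalling components, 0 passed in limma over all genes or adjusted over the list alone (4 at an unadjusted p under 0.05); Cd28 differed by −0.42, Lcp2 by −0.42, Cd247 by −0.33, with another probe set at 0.81, and Cd3e by 0.41. Their median was −0.13 (camera adjusted p = 0.00308; adjusted p = 0.738 with an estimated correlation; fry adjusted p = 0.388), and the adjusted p was 0.209 without Cre-positive sample 2. The median was −0.26 with arrays centred on their median and −0.21 without Cre-positive sample 1.

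Proliferation genes differed by a median of 0.70, but the arrays did not separate by group. Of 28 measured, 0 passed in limma over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05), with the replication helicase genes Mcm5 at 0.91 ± 0.28 (SE) and Mcm4 at 0.57 ± 0.18. The mean deviation of the list was −0.82 and 0.17 in Cre-negative samples 1 and 2 and −0.13 and 0.78 in Cre-positive samples 1 and 2, so Cre-positive sample 1 lay below Cre-negative sample 2. Camera gave an adjusted p of 0.00746 (adjusted p = 0.88 with an estimated correlation; fry adjusted p = 0.556). Without Cre-negative sample 1 the median was 0.18 and the camera direction turned to lower (adjusted p = 0.945), and without Cre-positive sample 2 the median was 0.19 (adjusted p = 0.813).

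**Figure D2:**
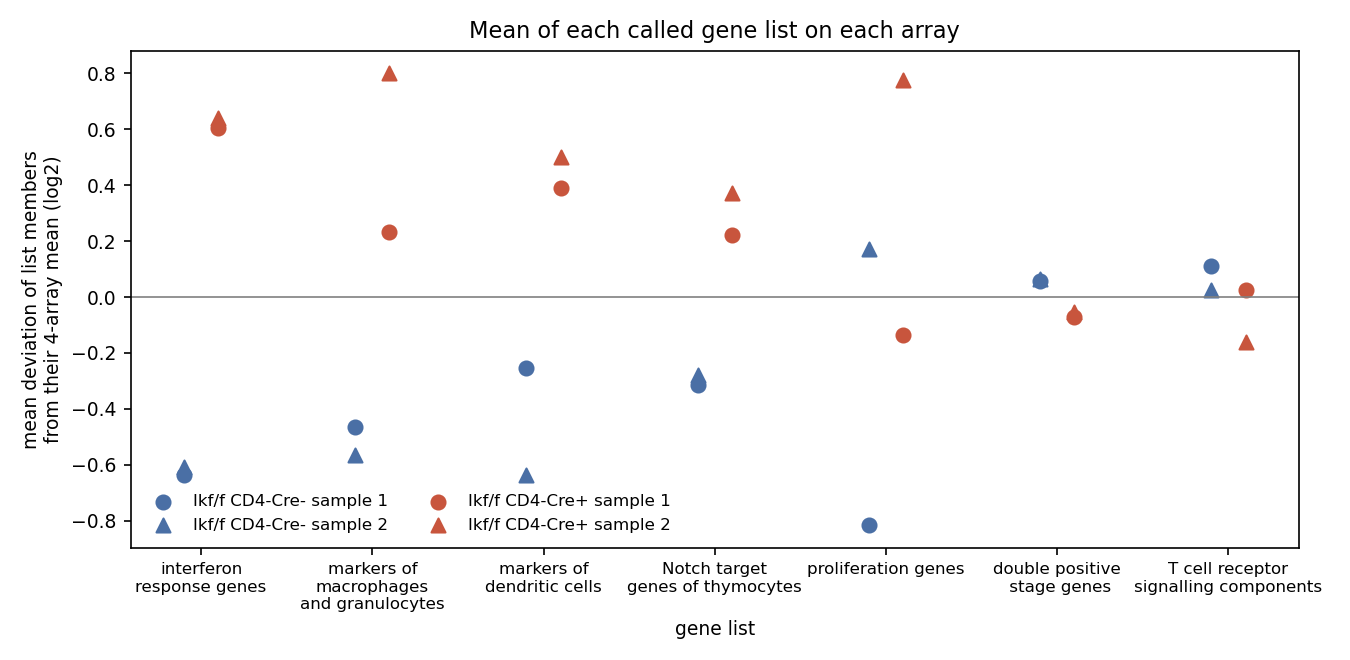
Mean deviation of the members of each called list from their own 4-array mean (vertical axis, log2) on each array. Blue and red points are Cre-negative and Cre-positive arrays, circles and triangles samples 1 and 2; the interferon list lay at −0.64 and −0.61 against 0.60 and 0.64, while the proliferation list overlapped between groups.

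Several lists that were not called held single genes that passed. Of 23 genes of positive selection and maturation, 3 rose in limma, Gimap4, the interleukin 7 receptor gene Il7r (1.12 ± 0.12, SE) and the tetraspanin gene Cd53 (1.32 ± 0.17), and 4 passed adjusted over the list alone; Itm2a differed by 0.94. Their median was −0.12, their mean 0.17 and the camera direction lower (adjusted p = 0.679); without Cre-positive sample 1 the median was −0.34 and the list was called (adjusted p = 0.0124). Of 19 T lineage transcription factors, Id2, an inhibitor of E proteins, rose by 2.12 ± 0.22, with 0 others passing in limma and 2 passing adjusted over the list alone. Without probe sets that can bind several transcripts Id2 differed by 0.24, and Lef1 differed by 0.66 in the full data. That list had a median of −0.06, a mean of 0.13 and a lower camera direction (adjusted p = 0.865). Among 12 Bcl2 family regulators, the proapoptotic gene Pmaip1 rose by 0.87 ± 0.12 and 5 passed adjusted over the list alone, 4 higher and 1 lower; Bak1 differed by 0.93 and Bcl2 by −0.82, though its probe sets reached 0.32, and the median was 0.29 (adjusted p = 0.144). Among 18 cytokine and chemokine receptors only Il7r passed in limma, also adjusted over the list alone, while Il21r differed by −0.56 and Ifngr1 by −0.51, with a median of −0.02 (adjusted p = 0.362). Among 5 cytotoxic genes the granzyme gene Gzma rose by 1.43 ± 0.19 and 2 passed adjusted over the list alone; Ccl5 differed by 0.62 and the median was 0.26 (adjusted p = 0.232).

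None of 25 Polycomb subunits and none of 14 NuRD subunits passed in limma, over all genes or adjusted over the list alone, and 5 and 3 had an unadjusted p under 0.05. The Polycomb median was 0.08 (adjusted p = 0.937), with Phc2 at 0.39 and Cbx8 at −0.36, and the NuRD median was 0.09 with a lower camera direction (adjusted p = 0.997), with Cdk2ap1 at 0.57 and Mbd2 at −0.38; both medians turned negative, to −0.05 and −0.04, with arrays centred on their median. Of the 5 Ikaros family genes only Ikzf1 passed, over all genes and adjusted over the list alone, with Ikzf2 at 0.21, though 1 of its 2 probe sets differed by −0.75, Ikzf3 at 0.23, a list median of 0.20 against a mean of −0.20, and a lower camera direction (adjusted p = 0.567). Of 10 early stress genes 0 passed over all genes in limma (1 at an unadjusted p under 0.05) and 1 adjusted over the list alone, Dusp1 (0.62), with Zfp36 at −0.31 a median of 0.05 that was −0.08 after centring, and a lower camera direction (adjusted p = 0.983). Of 5 B cell markers 0 passed over all genes in limma (1 at an unadjusted p under 0.05) and Ms4a1 (0.71) passed adjusted over the list alone, with a median of 0.13 (adjusted p = 0.679). Of 9 stromal and epithelial markers the growth factor receptor gene Pdgfrb rose by 1.05 ± 0.14 (3.24 in its other probe set), and 2 passed adjusted over the list alone. The list median was −0.12 against a mean of 0.58, with a lower camera direction (adjusted p = 0.997). The collagen gene Col1a2 read 5.18 and 5.33 in the Cre-negative and 11.55 and 8.01 in the Cre-positive samples. This difference of 4.52 ± 1.07 did not pass (limma adjusted p = 0.107), and the other Col1a2 probe set differed by 4.09. The 3 erythroid markers kept by the filter had a median of −0.18 and 0 passed in limma (0 at an unadjusted p under 0.05). Of the 4 sex-linked genes, which were not tested as a list, Xist, the transcript of the inactive X chromosome, read 12.75 in Cre-negative sample 2 and 4.73 to 5.37 on the other 3 arrays, where the Y-linked gene Kdm5d read 8.23 to 8.37 against 2.87. Cre-negative sample 2 thus had the pattern of a female and the other samples that of males.

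**Figure D3:**
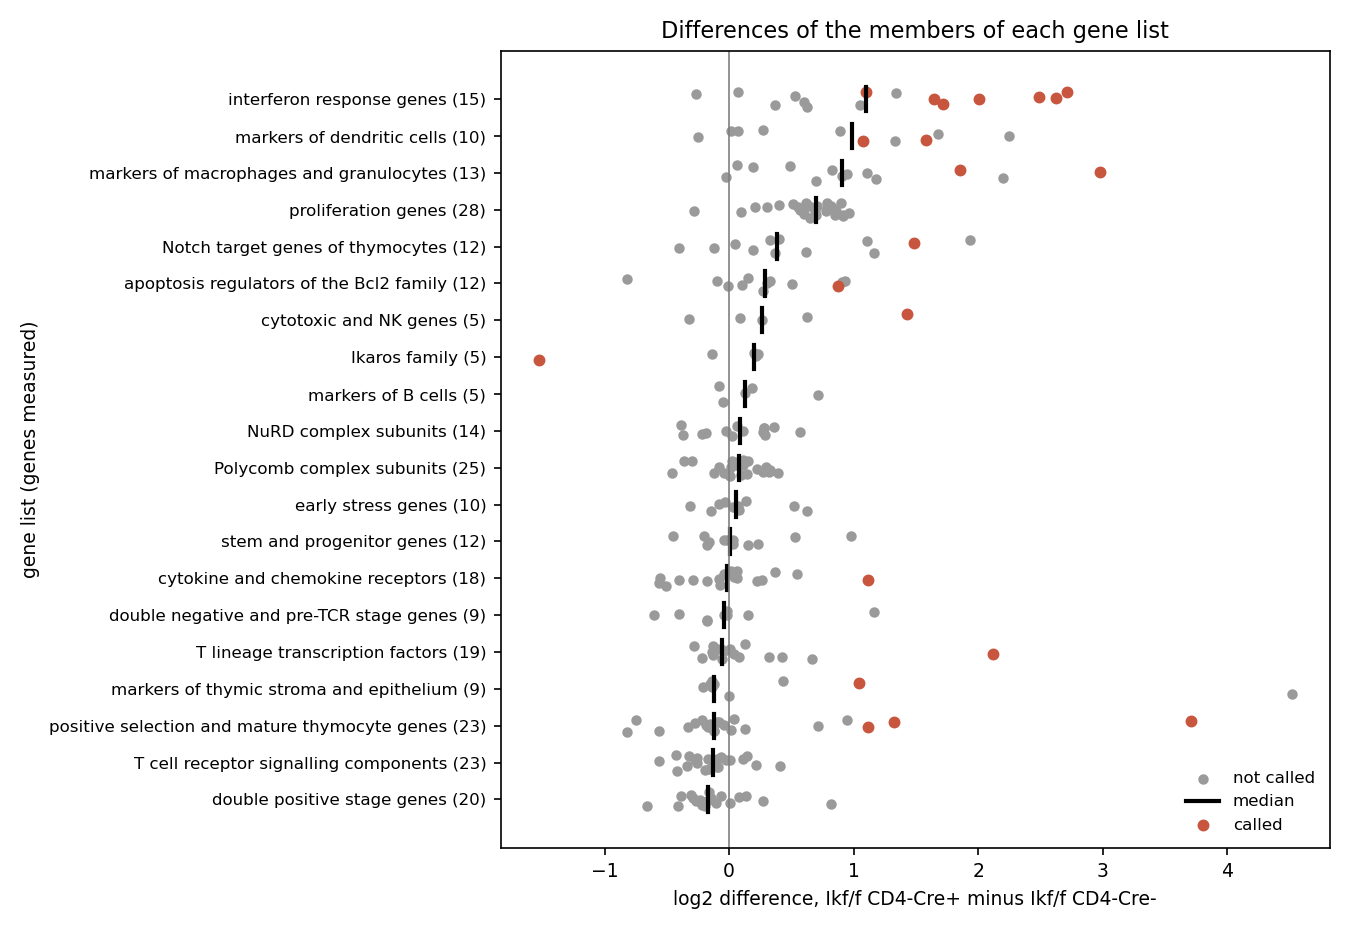
Log2 difference, Cre-positive minus Cre-negative (horizontal axis), of every kept member of each tested list (vertical axis, with the number of genes measured). Red points passed at an adjusted p under 0.05, grey points did not, and black bars are list medians, from 1.10 for interferon response genes to −0.17 for double positive stage genes.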

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

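All tests in this part were chosen after the result was seen. Probe sets without a gene name played no part in the comparison of genes, yet many of them differed between the groups. When all probe sets above the signal filter were tested together in limma, 277 of the 3881 unnamed ones passed, 22 higher and 255 lower in the Cre-positive mice. That is 6.57% lower, against 0.88% of the 20967 probe sets with 1 gene. The largest changes were increases of 3.30 and 3.01 and decreases of −1.86 and −1.78, and the files used do not pair these probe sets with genes. The median difference was −0.22 for unnamed and 0.04 for named probe sets, and 71.7% of the unnamed lay below 0.

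Unnamed probe sets were dimmer, with a median level of 6.56 against 7.36, so a normalization that depended on signal might lower them. Compared with named probe sets of the same mean level, however, their median gap was still −0.25, and it was −0.22 to −0.31 in every pair of a Cre-positive with a Cre-negative array, against 0.06 and 0.02 within the groups. The female pattern of Cre-negative sample 2 is argued against as well, since the gap was −0.28 without that array. A group difference in RNA quality or labelling stays open: in 5348 genes with more than 1 named probe set, the next brightest moved by −0.043 relative to the brightest (−0.03 to −0.06 over pairs of a Cre-positive with a Cre-negative array, 0.02 and 0.01 within the groups), the direction that such a difference could give. This shift is far smaller than the gap and 2 arrays per group do not settle its cause. Loss of Ikaros and Cre itself, which separate the groups in the same way, remain untested biological explanations.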

How the results depend on the processing

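The proliferation covariate was chosen after the data were seen; the other alternatives were planned. Of the 56 called genes named in the text, 54 kept their direction in every alternative run and 30 stayed past the threshold in all alternatives with 4 arrays other than that covariate; Ppic and Jchain alone stayed past it in every alternative. Against 160 calls (129 higher, 31 lower), there were 90 (68 higher) with the filter at the 60th percentile and 104 (73 higher) without probe sets that can bind several transcripts; a trend and robust prior gave 301 (222 higher, 79 lower), the covariate 310 (262 higher, 48 lower), median centring 75 higher and 48 lower, and every probe set on its own 48 lower. With the replicate block there were 821 calls (628 higher, 193 lower), all 160 among them, but the labels of same-numbered samples share only a number. Across genes, the difference between samples 1 and 2 correlated at 0.177 between the groups. The proliferation list, however, was higher in sample 2 than in sample 1 of both groups. The block ended no list call. Leaving out 1 array gave 3 to 99 calls, 3 to 95 higher and 0 to 4 lower; the 0, in limma without Cre-negative sample 2, came with 2296 genes at an unadjusted p under 0.05. The Ikzf1 difference then lay between −1.693 and −1.368 and was no longer past the threshold. A group left with 1 array has no spread of its own, and why the call was lost was not tested. With all 4 arrays the dimmer Ikzf1 probe set gave −0.223. With estimated correlations 0 of 20 lists were called by camera, 2 at an unadjusted p under 0.05, against 7. Among those 7, the estimated correlation was 0.946 for proliferation, 0.221 for T cell receptor signalling and 0.084 for dendritic cell markers. For the interferon, macrophage, Notch and double positive lists it lay between −0.086 and 0.005, under the preset 0.01. Correlated genes thus do not account for the lost calls of these lists. Their p at the preset correlation, however, does not measure the spread between mice. Without probe sets that can bind several transcripts, Ddr1 turned to −0.124, Dtx1 to −0.574 and Igll1 to 0.130. With the mean of all probe sets, Igll1 turned to 0.057, Ikzf2 to −0.241, Xaf1 to −0.385 and Cd247 to 0.049. After median centring Fcer1g turned to −0.066, Siglech to −0.117 and Cst3 to −0.061, and Siglech turned to −0.015 with quantile normalization. With 1 array left out, Igll1 ranged from −0.065 to 0.033, Adgre1 from −0.15 to 0.095, Fcer1g from −0.012 to 0.137 and Siglech from −0.174 to 0.198. The proliferation list ranged from 0.180, with the direction turned, to 1.256 with 1 array left out, and was −0.044 with its own mean as covariate, which removes it by construction. Some list calls appeared: without the filter, Bcl2 family regulators (adjusted p = 0.0336), cytotoxic genes (0.0017) and B cell markers (0.0168), and with the mean of all probe sets, cytokine and chemokine receptors (0.0405), all by camera with Benjamini-Hochberg adjustment. The T cell receptor list lost its call with the covariate (adjusted p = 0.155). Other causes were not tested. No measure of signal over background was used here, and 23 of the called higher genes had Cre-negative means under the signal filter, where RMA values compress differences.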

Other observations

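The tests of the marker lists and the interferon list, the within-group differences set beside them and the comparison of array splits were chosen after the results were seen; the test of neighbouring genes was written before its result. The genes in this paragraph passed in limma but were chosen after their values were seen. Ifitm3, which encodes a membrane protein that blocks virus entry, rose by 2.50 ± 0.15 (difference ± SE, n = 2 per group), Trim30d by 2.13, the ADP-ribosyltransferase gene Parp12 by 1.87 and the GTPase gene Irgm1 by 1.48. Vcl, which encodes vinculin, rose by 2.44 and the semaphorin receptor gene Nrp1 by 1.34. Ctnnd1, which encodes p120 catenin, rose by 2.18, but without probe sets that can bind several transcripts it differed by 0.49 (limma adjusted p = 0.187). Tmem176b rose by 1.90, the serine synthesis gene Phgdh by 0.94, the amino acid transporter gene Slc7a5 by 1.15 and Pck2 by 1.22. Tox2 rose by 1.19 and the receptor gene Notch2 by 0.83, while the DNA demethylase gene Tet2 fell by 0.93, Arid3b by 0.76 and the receptor gene Gpr174 by 1.06. With arrays centred on their median, Notch2, Phgdh and Slc7a5 no longer passed (0.70, 0.81 and 1.02), and with the mean of all probe sets Ctnnd1, Nrp1, Notch2, Phgdh, Tox2, Tet2 and Arid3b did not. Slc7a5 and Arid3b also missed the threshold without probe sets that can bind several transcripts.

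As lists, markers of macrophages, granulocytes and dendritic cells were higher in the Cre-positive mice by camera at the preset correlation, but both had an adjusted p = 0.456 with an estimated correlation, and fry gave the dendritic list an adjusted p of 0.117. Granulocyte RNA in Cre-positive sample 2 alone is argued against as the whole cause. In Cre-positive sample 1 the 4 granulocyte genes lay at −0.09 relative to the controls, yet the other 20 markers lay 0.752 higher in median. Their median differed by −0.004 between the Cre-negative arrays and by −0.03 between the Cre-positive arrays. Single markers differed more between the Cre-negative arrays: H2-Aa, H2-Ab1 and H2-Eb1 read 7.01, 6.74 and 6.07 in sample 1 and 5.89, 6.13 and 5.30 in sample 2. Csf1r went the other way (5.66 and 5.98). The mean deviation of the dendritic list was −0.25 and −0.64 in Cre-negative samples 1 and 2. RNA of macrophages or dendritic cells in the Cre-positive samples could still contribute. Of the 20 markers, all kept by the signal filter, 15 were higher in both Cre-positive arrays than in both controls. Markers below the filter other than granulocyte genes were Itgam, Cd14, Fcgr3, Cd68, Mrc1, Xcr1 and Ccl17. At their low signals they differed by only −0.01 (Xcr1) to 0.24 (Mrc1). Of the 20, 17 had control means at or above the signal filter. Another list holds 0 of them, but this follows from how the lists were written. It does not show that the marker rise is separate from the interferon response. Lyz2 differed by 1.85 and C1qa by 1.11, but the other 5 markers, Csf1r (0.19), Fcer1g (0.06), Siglech (0.01), Adgre1 (−0.03) and Ccl22 (−0.25), and Cst3 (0.07, with a Cre-positive mean of 10.07) were named after their values were seen and did not pass in limma; Fcer1g, Siglech and Cst3 turned negative after centring, and Csf1r differed by 1.21 (adjusted p = 0.042) without probe sets that can bind several transcripts. The method of cell isolation is not given in the sources used here. Expression of these genes by the thymocytes themselves, which Ikaros loss or Cre itself might cause, cannot be told apart from such RNA. Both predict higher values in both Cre-positive arrays.

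The female control and a constant offset between arrays are argued against as the whole cause of the higher interferon response genes. The list median was 0.985 without Cre-negative sample 2 and 0.969 with arrays centred on their median. Centring subtracts 1 value per array, so it does not address scaling that depended on signal. Between arrays of one group the list median differed by −0.05 and −0.07, and by −0.08 and −0.09 after centring. Camera called the list at the preset correlation but not at the estimated one (adjusted p = 0.444 with an estimated correlation). The estimated correlation was 0.005, under the preset 0.01, so correlated genes do not account for the lost call. The p at the preset correlation, however, does not measure the spread between mice. Of the 15 genes, 14 were higher in both Cre-positive arrays than in both controls. An effect of Ikaros loss or of Cre itself in the thymocytes is a hypothesis that remains open. So does interferon exposure that differed between the mice or RNA of other cells, which the design did not test.

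The 3 splits of the 4 arrays are too few for a share under 0.05; the real split, 1 of the 3, called 160 genes in limma, and the highest of the others called 0 (69 and 204 genes at an unadjusted p under 0.05 in the others). A stretch of DNA of another strain linked to the Cre transgene could raise or lower neighbouring genes together. Only 3 pairs of called genes were neighbours in the gene order, with interferon list members and families sharing a symbol stem left out, against a mean of 1.92 and a 95% range of 0 to 5 in 10000 permutations (one-sided permutation p = 0.298), which argues against a linked stretch as the source of most calls; a stretch with few called genes would not be seen.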
